A study of Bacillus subtilis subsp. subtilis str. 168 with 6 samples.

How the data were processed

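RNA of 6 samples was measured, 3 of a ccpA mutant and 3 of a ccpA topA(S478P) mutant of Bacillus subtilis 168, and each array belonged to the group that its label gives. Per the labels, total RNA (5 µg) was labelled with Cy5 and hybridised with a Cy3-labelled pool of equal amounts of RNA from all samples, and the replicates were biological. The authors deposited 1 scanner file per array, whose spot intensities are median Cy5 and Cy3 pixel values on a linear scale with a median background for each channel, per the file headers and columns. The analysis had been planned for mean signals; the files hold medians, which were used with the same test. Feature Extraction version 11.5.1.1 stands in the file headers and version 10.5 in the submitters' processing notes, and the conflict was not resolved. The scanner's own log10 ratio, used in 1 alternative, was made by Feature Extraction; its statistics in the files give a spatial detrending fit and linear and lowess dye-normalization factors for each channel. The deposited series matrix holds log10 ratios of Cy5 to Cy3, which differed from the scanner's own log10 ratio by less than 0.005 for each probe. The deposited gene-level table holds linear ratios of Cy5 to Cy3, which the authors made with a normalization that is not given in the sources used here; their log2 values correlated with the per-gene median of the scanner's log ratios at r of 0.9996 or more on all 6 arrays. The median ratio per array in that table lay between 0.944 and 1.13, and the median log10 ratio in the series matrix between -0.0269 and 0.0384, so neither table is centred on a ratio of 1.

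Each array had 45152 spots, of which 1417 were controls and 43735 were probes, each spotted once. Signals were background-corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3 and normalized by loess within each array with control spots at weight 0. Control spots and spots with an outlier flag (between 140 and 1059 per array) were then left out, and no spot was saturated. The value of a feature was the median over its probes (1 to 15, with a median of 9 for annotated genes), so that probes which disagree, as in ccpA, are reduced to 1 value. The 5855 features comprised 4230 annotated genes, 1571 RNA segments and 54 miscellaneous RNAs. A feature was kept if 50% or more of its probes were well above background in Cy5 on all 3 arrays of at least 1 group, which kept 5723, of which 4179 were annotated genes. Of the annotated genes, 4226 matched the reference annotation (assembly ASM904v1) by locus tag; it replaced 681 symbols of the array files and gave the order of genes, and none of its coordinates is reported.

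The difference, ccpA topA(S478P) minus ccpA, was tested on the log2 scale with limma's lmFit and eBayes over all 6 arrays, two-sided, with Benjamini-Hochberg adjustment over all features kept and a threshold of 0.05. Errors of differences are the standard errors of that fit. Before the data were examined, 34 gene lists, the rule for named genes, the tests and the alternatives had been fixed. The lists cover central, amino acid and nucleotide metabolism, translation, energy, stress regulons, a prophage and the cell states a culture can hold, and 651 of their 653 members were on the arrays. A list's symbols were looked up among those of the array files first and then among those of the reference. Lists with at least 5 members kept were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated for each list and with fry. The named genes are 17 fixed in advance, the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, with at most 2 that share their first 3 letters, and up to 3 called members of each list with the largest change, which makes 86 genes. A further 6 lists were written after the data had been seen and are described with counts and medians, without a test of the list.

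The tests were first run on simulated data, made from the means and residual spreads of 5678 features with no missing value, with known changes in a set of genes for the comparison of the 2 strains. A log2 change of 2 was recovered in 53 of 66 genes, a change of 1 in 23 of 67 and a change of 0.5 in 1 of 67, with 6 false calls among 83. The changed genes were a far smaller share of the features than the 26.8% called in the real data. The adjustment depends on that share, so these rates do not carry over to the real comparison. Of the 34 lists, camera called the 1 that had been shifted by 1 and 0 of the others, in data without correlation between genes. Alternatives covered the background correction, the normalization, the authors' deposited values, the filter on dim probes, the summary over probes, the variance model, the Cy5 signal alone, the replicate number or slide as a block, the threshold, and leaving out each sample. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.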

Results

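Transcripts of Bacillus subtilis 168, a Gram-positive soil bacterium that can form spores and take up DNA, were measured on 6 two-colour Agilent arrays. Both strains are ccpA mutants per the labels; ccpA encodes the carbon catabolite control protein, which represses and activates genes in the presence of glucose. A second mutation, topA(S478P), was present in 1 of the strains; topA encodes DNA topoisomerase I, which relaxes negatively supercoiled DNA. Each strain was represented by 3 biological replicates per the labels. Cells were grown at 37 °C in a minimal medium with 5 g/l glucose and 8 g/l potassium glutamate and taken at an OD600 of 1. The titles of all 6 samples give exponential growth. The Cy5 channel held the sample and the Cy3 channel a pool of RNA, so that each value below is a log2 ratio of sample to pool. The median Cy5 signal lay between 783 (ccpA topA(S478P) replicate 3) and 1824 (ccpA replicate 2) against a median background of 50 to 54, and between 95.6% and 98.3% of the 43735 probes were well above background in Cy5. The number of arrays limits the precision.

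The arrays were placed on 3 slides. Slide 1 held replicate 1 of both strains, slide 2 held ccpA replicate 3 and ccpA topA(S478P) replicates 2 and 3, and slide 3 held ccpA replicate 2, which was scanned on another date. With the slide as a block, that array therefore has a term of its own and does not enter the difference. The block also leaves less information for the error, so a call lost with it does not by itself show a slide effect. Across features, which are not independent replicates, the 3 ccpA arrays correlated with one another at r between 0.76 and 0.80. ccpA topA(S478P) replicates 1 and 2 correlated at r = 0.89, whereas replicate 3 reached r = 0.43 with replicate 1 and r = 0.50 with replicate 2. Arrays of different strains correlated negatively, from r = -0.42 to r = -0.16; the labels give Cy5 to the sample on all 6 arrays and the pool contains both strains, so the direction was kept.

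The first question was whether the 2 genes named in the genotypes could be checked on the arrays. The topA transcript had a log2 ratio of 0.56 ± 0.40 (SD, n = 3) in ccpA and 0.12 ± 0.20 (SD, n = 3) in ccpA topA(S478P), a difference of -0.45 ± 0.24 (SE) that did not pass the test (limma adjusted p = 0.219). A base substitution leaves the transcript in place, so this level checks nothing about the label. The ccpA gene lay at -0.45 ± 0.04 (SD, n = 3) and -0.23 ± 0.21 (SD, n = 3), with a difference of 0.23 ± 0.16 (SE, limma adjusted p = 0.344). Its probes were well above background in both strains. The 6 probes over bases 18 to 434 of the gene had a mean log2 ratio of 0.38 ± 0.28 (SD over the 6 arrays), and the 7 probes over bases 441 to 980 had -0.54 ± 0.09. The step lay at the same place on all 6 arrays. A ccpA level near background in both strains had been planned as a check of the labels, and it was not found. The labels do not say which part of ccpA was removed or interrupted, so these values do not decide the genotype. The other topoisomerase genes gave no call: gyrA differed by 0.06 ± 0.15 (SE), gyrB by 0.10 ± 0.15, parC by 0.09 ± 0.15 and parE by 0.01 ± 0.15. The largest change among them was in topB, at 0.54 ± 0.17 (limma adjusted p = 0.0639). In the list of topoisomerases and nucleoid proteins 0 of the 7 genes passed, also when adjusted over the list alone.

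**Figure D1:**
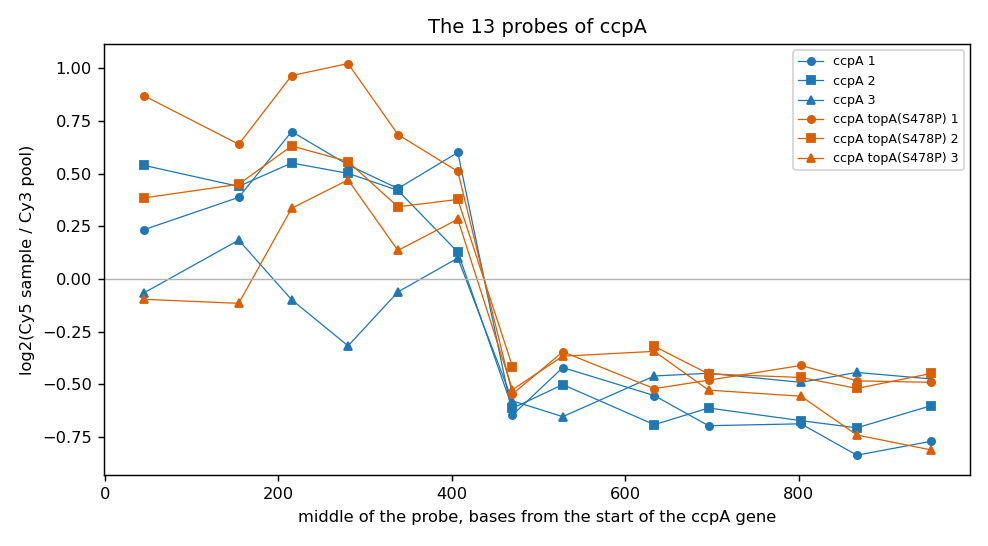
Log2 ratio of Cy5 sample to Cy3 pool (vertical axis) for the 13 probes of ccpA against the middle of each probe in bases from the start of the gene (horizontal axis), with 1 line per sample. On all 6 arrays the values step down between base 434 and base 441.

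The main comparison asked how the transcriptome of ccpA topA(S478P) differed from that of ccpA. Both strains were taken at the same OD600 and at no other point. A difference in growth state between the cultures thus cannot be told apart from an effect of the topA mutation. Transcripts of most genes in the lists for early sporulation, competence and cannibalism toxins and of part of the motility genes were lower in ccpA topA(S478P). Those of most glycolysis genes, of 11 of 17 purine genes and of 5 of 10 pyrimidine genes were higher. As lists, these were called by camera at its preset correlation, but 0 of the 34 lists were called with an estimated correlation. Of these lists, motility alone was not called by fry. Of 5723 features kept, 548 were higher and 988 lower in ccpA topA(S478P) (limma, adjusted p under 0.05); 435 and 763 of these were annotated genes and most of the others RNA segments. At least 2-fold differences were called for 951 features, of which 184 were higher and 767 lower, and 98 features fell by 16-fold or more. The groups did not overlap for 2582 features (45.1%), where chance gives 10%. With the slide as a block, 102 features were higher and 660 lower, and 753 of the 1536 called features stayed called. Within slide 1 and within slide 2, 1530 of the 1536 had the direction of the fit over all arrays. That count follows in part from the selection, since the features were called from the same arrays. The split depended on the scaling: the authors' gene-level values gave 945 higher and 881 lower. They place the median of all features 0.23 log2 units higher in ccpA topA(S478P), against 0.06 here. Shifted by 1 constant to the median used here, an alternative added after seeing the data, they gave 630 higher and 1005 lower. That shift thus accounts for most of the difference in the split, but not for that in size, since 1285 features changed at least 2-fold with the authors' values and 1200 after the shift. Changes near 0.2 are therefore relative to the scaling. The rises also depended on single arrays: leaving out ccpA replicate 1, 2 or 3 gave 259, 221 and 223, and leaving out ccpA topA(S478P) replicate 1, 2 or 3 gave 377, 202 and 818. There were 549 without both arrays numbered 3, an alternative chosen after seeing the data.

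Most sporulation genes fell. Of the 24 genes in the early sporulation list, 22 fell (23 adjusted over the list alone), with a median difference of -2.45, and none rose. spoVID and spoIVA, whose products form the basis of the spore coat, fell, with differences of -5.81 ± 0.30 (SE) and -5.48 ± 0.20 (limma adjusted p = 4.74e-05 and 2.09e-05), and spoIIQ, which is needed for engulfment, differed by -4.69 ± 0.21 (limma adjusted p = 3.45e-05). sigE and sigF, the early sporulation sigma factors of the mother cell and the forespore, fell, with -2.83 ± 0.26 and -1.90 ± 0.31. spo0A, the master regulator of sporulation, differed by -0.72 ± 0.24 and did not pass over all features (limma adjusted p = 0.0629). It passed only when adjusted over the list alone. spo0A and both sigma factors were named after their values were seen. Of the 8 largest falls by the rule for named genes, 7 were in genes of the late spore and the other was in skfA, a cannibalism gene described below. cotG, of the spore coat, went from 1.91 ± 1.50 (SD, n = 3) to -6.32 ± 0.42 (limma adjusted p = 0.000296), and cotX, also of the coat, from 1.90 ± 1.39 to -5.80 ± 0.25 (limma adjusted p = 0.000263). gerQ, a coat protein, differed by -6.87 ± 0.22 (SE), sspB, a small acid-soluble protein that coats spore DNA, by -6.51 ± 0.24, spoVIF by -6.48 ± 0.69, cgeA by -6.34 ± 0.67 and sscA by -6.21 ± 0.73, and all 5 passed the test. The single probe of sscA was well above background on 2 of the 3 arrays of ccpA topA(S478P), so its size there is less certain. The early sporulation list was called by camera (adjusted p = 1.73e-14) and by fry (adjusted p = 0.00112). With an estimated correlation, camera gave it an adjusted p of 0.504. A slide block left 20 of its genes called as lower and its median difference was -2.55, against -2.16 within slide 1 and -2.72 within slide 2.

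In lists of later stages, written after the data had been seen, the median of each ccpA topA(S478P) sample was below that of each ccpA sample. Of 8 forespore genes under sigma factor F, 5 fell, of 23 mother-cell genes under sigma factor E, 22 fell, of 23 forespore genes under sigma factor G, 17 fell, and of 30 mother-cell genes under sigma factor K, 29 fell; the first 2 lists share 2 and 13 genes with the early sporulation list. Among the ccpA samples the sigma factor K list had a median of 2.33, 1.70 and 0.46 in replicates 1, 2 and 3, so replicate 3 was lower, while the sigma factor E list had 1.45, 1.52 and 1.77. In ccpA topA(S478P) the sigma factor K list lay between -2.25 and -1.82. usd, 1 of the mother-cell genes, was not well above background on any array of ccpA topA(S478P) and was at least 29.9-fold lower there. That bound sets the mean of the bright group against the higher of the dimmest signal well above background and the gene's own signal.

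**Figure D2:**
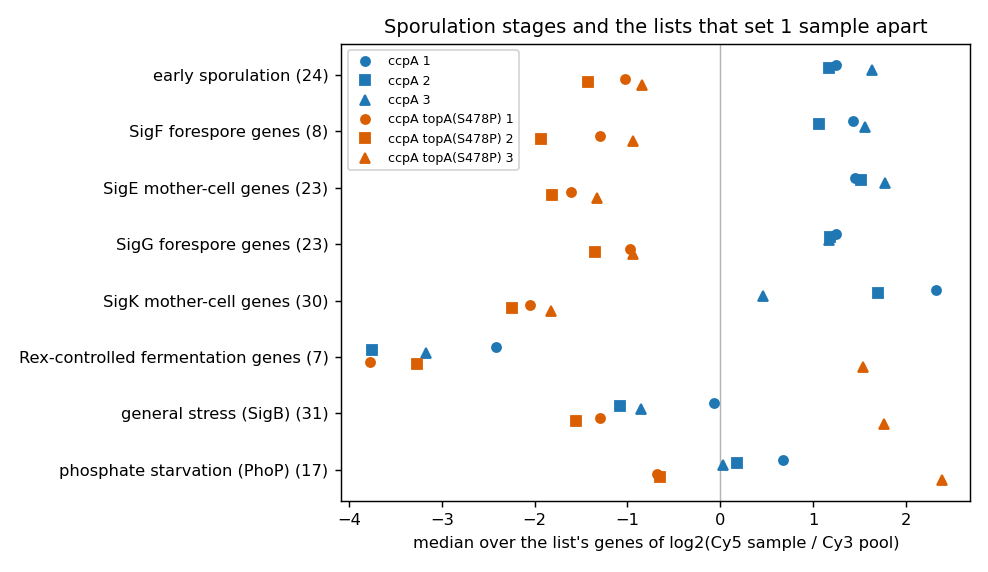
Median over each list's genes of the log2 ratio of Cy5 sample to Cy3 pool (horizontal axis), with 1 point per sample and the number of genes in brackets. The early sporulation list lies between 1.17 and 1.64 in ccpA and between -1.42 and -0.85 in ccpA topA(S478P); ccpA topA(S478P) replicate 3 alone reaches 1.77 for the general stress list and 2.39 for the phosphate starvation list.

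All competence genes and most cannibalism genes of the lists fell. All 19 genes of the competence list fell (19 adjusted over the list alone), with a median of -3.43. They included comK, the master regulator of competence, at -2.23 ± 0.32 (SE), ssbB, a single-stranded DNA-binding protein, at -4.20 ± 0.39, comFA, a DNA translocase, at -3.73 ± 0.33, and comGB, of the DNA-uptake machinery, at -3.63 ± 0.42 (limma adjusted p = 0.00278, 0.000401, 0.000312 and 0.001). comK was named after its value was seen. Of the 12 genes for cannibalism toxins, with which sporulating cells kill siblings, 10 fell (10 adjusted over the list alone), with a median of -3.17; skfA went from 2.15 ± 0.38 (SD, n = 3) to -3.94 ± 0.76, and skfB and skfC fell, with differences of -4.77 ± 0.21 (SE) and -4.14 ± 0.18. In the fit with the slide as a block, 18 and 8 genes of the 2 lists fell. The medians were -3.47 and -3.16 with that block, -3.77 and -3.15 within slide 1, and -3.03 and -3.19 within slide 2. Both lists were called by camera (adjusted p = 3.48e-12 and 9.77e-09), but had adjusted p = 0.587 and p = 0.504 with an estimated correlation. They were also called by fry (adjusted p = 0.00464 and 0.00049).

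Part of the motility and envelope stress genes was lower. Of the 47 motility and chemotaxis genes under sigma factor D, 16 fell and 31 were not called (18 fell when adjusted over the list alone), with a median of -0.78. flgM, the anti-sigma factor of that regulon, fell by 2.13 ± 0.28 (SE), and flgN and flgL fell with differences of -1.77 ± 0.23 and -1.58 ± 0.25; hag, the flagellin gene, named after its value was seen, fell by 1.29 ± 0.27. The list's median was -1.44 within slide 1 and -0.56 within slide 2, and -0.92 with the slide as a block, where 9 of the 47 genes fell and flgL (limma adjusted p = 0.0518) and hag (0.0704) were not called. Of the 27 genes of the envelope stress list under sigma factor W, 17 fell (19 adjusted over the list alone), with a median of -0.80, and yuaI, floT and nfeDB had differences of -1.61 ± 0.26, -1.60 ± 0.27 and -1.45 ± 0.28; its medians were -0.83 with the slide as a block, -1.11 within slide 1 and -0.63 within slide 2. With that block 3 of the 27 genes fell, and none of the 3 named was called (limma adjusted p = 0.0569, 0.0508 and 0.0738). camera called both lists (adjusted p = 5.90e-08 and 5.84e-06), with adjusted p = 0.779 and p = 0.652 with an estimated correlation. The motility list was not called by fry (adjusted p = 0.0802) and the envelope stress list was (0.0145).

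Most genes of glucose uptake and glycolysis rose, and 2 genes of the reverse route fell. Of the 17 genes in the glycolysis list, 14 rose and none fell (15 rose when adjusted over the list alone), with a median of 1.104. Apart from pfkA, those called lie in runs of neighbouring genes: ptsG to ptsI, cggR to eno, and pdhA to pdhD of pyruvate dehydrogenase. The list's pgi, fbaA and pyk were not called (limma adjusted p = 0.0502, 0.492 and 0.197). ptsG, the glucose-specific permease of the phosphotransferase system, rose from -1.07 ± 0.14 (SD, n = 3) to 0.66 ± 0.23, a difference of 1.73 ± 0.18 (SE, limma adjusted p = 0.000593). pdhB, of pyruvate dehydrogenase, rose by 1.43 ± 0.20 and gapA, the glycolytic glyceraldehyde-3-phosphate dehydrogenase, by 1.38 ± 0.27 (limma adjusted p = 0.00223 and 0.00967; 0.0338 and 0.0841 with the slide as a block). gapB and pckA, which serve gluconeogenesis, fell, with differences of -2.76 ± 0.27 and -2.16 ± 0.21 (limma adjusted p = 0.000496 and 0.000534; 0.0118 and 0.0156 with the slide as a block). Within slide 1 gapB differed by -2.69 and within slide 2 by -3.10, and the glycolysis list had medians of 0.55 and 1.35 there, with 1.06 under the slide block, where 5 of the 17 genes rose. camera called the list (adjusted p = 1.45e-07), with adjusted p = 0.504 with an estimated correlation, and fry also called it (adjusted p = 0.00464).

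Other carbon routes moved in both directions. In the citric acid cycle list, 2 of 12 genes fell (0 adjusted over the list alone), odhB with -0.67 ± 0.16 and odhA with -0.60 ± 0.17, which encode 2-oxoglutarate dehydrogenase. These 2 calls depended on the processing. With median centring odhB and odhA differed by -0.42 and -0.30 (limma adjusted p = 0.239 and 0.424), the scanner's log ratios and the authors' values gave odhA an adjusted p of 0.0767, and the Cy5 signal alone gave it 0.054. Neither was called with the slide as a block (0.102 and 0.1) or the replicate block (0.0578 and 0.0744), or without ccpA replicate 1 (0.084 and 0.111), 2 (0.0566 and 0.07) or 3 (0.0837 and 0.122) or ccpA topA(S478P) replicate 1 (0.0745 and 0.112) or 2 (0.105 and 0.134). The differences of odhB and odhA did not shrink with these blocks, at -0.74 and -0.70 with the slide and -0.67 and -0.60 with the replicate number. citZ (citrate synthase) differed by -0.34 ± 0.16 and citB (aconitase) by 0.20 ± 0.21, and neither passed, though citZ was called without ccpA topA(S478P) replicate 3 (-0.45, 0.0497). In the list of acetate, acetoin and lactate metabolism, 3 of 10 genes rose and 1 fell, as when adjusted over the list alone: alsS and alsD, of acetoin synthesis, rose by 1.01 ± 0.18 and 0.77 ± 0.16, and ackA, acetate kinase, by 0.88 ± 0.15. None of the 3 was called with the slide as a block (limma adjusted p = 0.0572, 0.0779 and 0.0596), though the differences there were 1.015, 0.80 and 0.85. Nor was alsD called without ccpA replicate 2 (0.0518) or 3 (0.0531) or ccpA topA(S478P) replicate 2 (0.067). Of 67 genes in operons under carbon catabolite repression, 12 rose and 6 fell, also when adjusted over the list alone; with the slide as a block 2 rose and 3 fell. The 3 largest changes were falls in mmgA, mmgB and mmgC, with differences of -4.12 ± 0.29, -4.43 ± 0.26 and -4.36 ± 0.23, which belong to a mother-cell metabolic operon. hutH, histidine ammonia-lyase, rose by 2.17 ± 0.31 as did the other hut genes in the list. Among the largest rises by the rule for named genes were also sacP and sacA, for sucrose uptake and cleavage, at 2.89 ± 0.39 and 2.72 ± 0.41, ywdA, beside them, at 2.50 ± 0.40, levB, a levanase, at 2.22 ± 0.28, cidA and cidB at 2.46 ± 0.52 and 2.38 ± 0.51, and yybF, which was 7.99-fold higher. With the slide as a block, limma adjusted p was 0.0422 for sacP, 0.0553 for sacA and for ywdA, 0.118 for cidA and 0.112 for cidB; cidA and cidB were also not called without ccpA replicate 2 (0.0617 and 0.0653) or 3 (0.055 and 0.053). In a list of 11 sucrose and levan genes, written after the data had been seen, 4 rose, 7 were not called and the median difference was 0.05, so the rise did not extend over the list.

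Glutamate metabolism was the next question, since the medium held glutamate and ccpA mutants are known for poor expression of the glutamate synthase genes. gltA and gltB, the subunits of glutamate synthase, had log2 ratios of -4.09 ± 0.34 and -4.16 ± 0.22 (SD, n = 3) in ccpA and of -2.19 ± 1.07 and -2.36 ± 0.93 in ccpA topA(S478P). The differences were 1.90 ± 0.52 (SE) and 1.80 ± 0.45 (limma adjusted p = 0.0365 and 0.0264), with no overlap of the 3 samples per group. Replicate 3 of ccpA topA(S478P) was the highest, with -0.97 for gltA and -1.29 for gltB. With the slide as a block both differed by 1.59 and the adjusted p was 0.162 and 0.153; within slide 1 the differences were 1.12 and 1.22 and within slide 2 1.95 and 1.88. Leaving out ccpA replicate 1, 2 or 3 ended both calls, at an adjusted p between 0.0668 and 0.121, and leaving out ccpA topA(S478P) replicate 2 ended that of gltA, at 0.0626. Both genes stayed called without ccpA topA(S478P) replicate 3 and without both arrays numbered 3. gltC, the activator of gltAB, differed by 0.27 ± 0.16, rocG, glutamate dehydrogenase, by -0.55 ± 0.19 and glnA, glutamine synthetase, by -0.05 ± 0.22, and none of these passed (limma adjusted p = 0.255, 0.0734 and 0.877). In alternatives, gltC was called with the Cy5 signal alone (0.46, limma adjusted p = 0.0495) and rocG without ccpA topA(S478P) replicate 3 (-0.66, 0.0307). glnR, the repressor of glnA, rose by 0.61 ± 0.17 (limma adjusted p = 0.0405). It was not called with the slide as a block (0.0735), the replicate block (0.0867) or the Cy5 signal alone (0.0563), though it differed there by 0.76, 0.61 and 0.64. Nor was it called without ccpA replicate 1 (0.12), 2 (0.051) or 3 (0.126), without ccpA topA(S478P) replicate 1 (0.116) or 2 (0.114), without both arrays numbered 3 (0.077), or with the authors' values shifted to the median used here (0.0731). In all, 3 of the 10 genes for glutamate synthesis and ammonium assimilation rose and none fell, also when adjusted over the list alone, and none was called with the slide as a block. Of the 14 genes of the nitrogen limitation list, 1 rose (1 adjusted over the list alone), nasA, a nitrate transporter, by 1.36 ± 0.26, which was not called with the slide as a block (0.093). camera called that list (adjusted p = 0.045) with adjusted p = 0.875 with an estimated correlation and 0.143 with the slide as a block. Its median was 0.43 in ccpA topA(S478P) replicate 3 and -0.50 and -0.52 in replicates 1 and 2, and the adjusted p was 0.3 without replicate 3 and 0.119 without ccpA replicate 2. The call also ended with the stricter filter on dim probes (0.0506), with the mean over probes (0.0507), by fry (0.291) and without both arrays numbered 3 (0.279). The median difference was 0.23 with the slide as a block, 0.05 within slide 1 and 0.39 within slide 2.

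**Figure D3:**
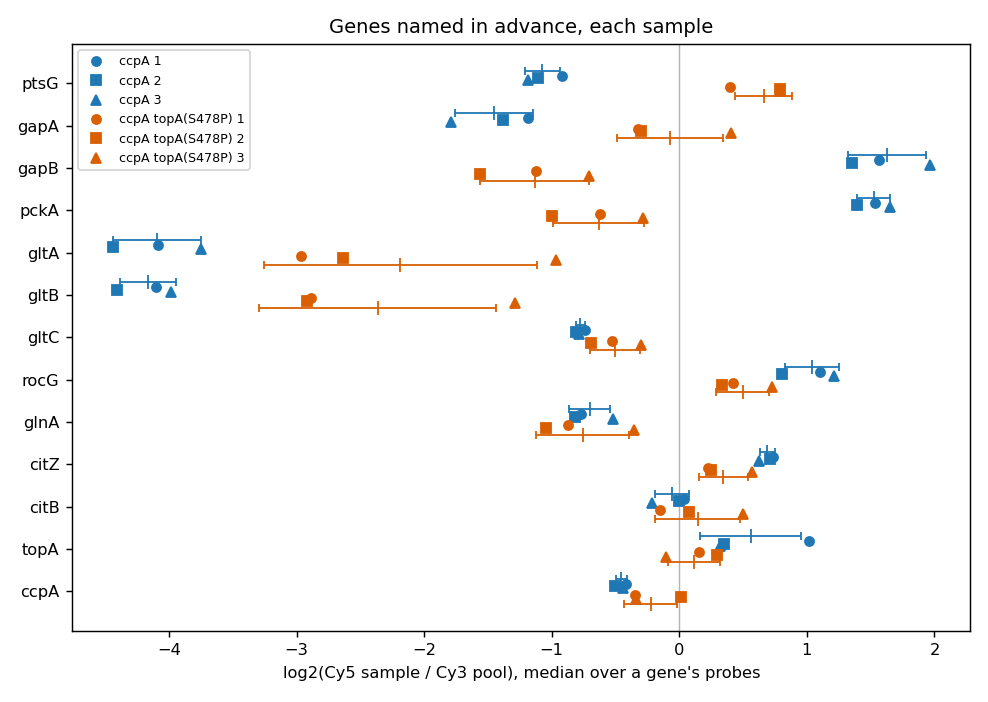
Log2 ratio of Cy5 sample to Cy3 pool (horizontal axis) for 13 of the genes named in advance, with 1 point per sample and, beside the points, the mean and SD of the 3 samples per strain. gltA lies at -4.09 ± 0.34 in ccpA and at -2.19 ± 1.07 in ccpA topA(S478P), and gapB at 1.63 ± 0.31 and -1.13 ± 0.43.

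Part of the nucleotide synthesis genes rose. Of 17 purine genes, 11 rose (15 adjusted over the list alone), with a median of 0.82; purA rose by 1.25 ± 0.29, pbuG, a purine transporter, by 1.13 ± 0.14 and purM by 0.93 ± 0.17. Of 10 pyrimidine genes, 5 rose (9 adjusted over the list alone), with a median of 1.17; pyrB, aspartate carbamoyltransferase, rose by 2.14 ± 0.44, pyrC by 1.98 ± 0.32 and pyrAA by 1.81 ± 0.26. The pyrimidine genes of the list, and the purine genes from purE to purD, are neighbours on the chromosome. Their counts are thus not counts of independent changes. The medians were 0.79 and 1.17 with the slide as a block, 0.84 and 1.42 within slide 1, and 0.82 and 1.55 within slide 2. With that block 1 purine and 4 pyrimidine genes rose, and purA and purM were not called (limma adjusted p = 0.109 and 0.0553). purA was also not called with the replicate block (0.0501) or without ccpA replicate 2 (0.07) or 3 (0.0672). camera called both (adjusted p = 2.69e-05 and 0.000451), with adjusted p = 0.652 and p = 0.504 with an estimated correlation, and fry also called both (adjusted p = 0.0254 and 0.00375). Of 31 genes of the PBSX prophage, a defective phage in the chromosome, 15 rose (26 adjusted over the list alone), with a median of 0.77, xtmA by 1.30 ± 0.23, xtmB by 1.25 ± 0.25 and xkdE by 1.17 ± 0.26; the median was 0.59 with the slide as a block, 0.37 within slide 1 and 0.75 within slide 2. With that block 0 of the 31 genes were called by limma, and xtmA, xtmB and xkdE had an adjusted p of 0.0758, 0.0812 and 0.107. xkdE was also not called with the replicate block (0.056) or without ccpA replicate 1 (0.0632) or 2 (0.07) or ccpA topA(S478P) replicate 2 (0.0512). camera's adjusted p = 1.77e-07 became p = 0.726 with an estimated correlation, and fry did not call the list (adjusted p = 0.0522). Of 23 aminoacyl-tRNA synthetase genes, 4 rose (0 adjusted over the list alone), with a median of 0.27: leuS by 0.71 ± 0.18, lysS by 0.57 ± 0.15, tyrZ by 0.55 ± 0.15 and metS by 0.53. The median of all features is 0.23 with the authors' values and 0.06 here, so a median of this size depends in part on the scaling. For the synthetase list camera's adjusted p was 0.00898, and 0.726 with an estimated correlation, and that of fry was 0.0475. The median was 0.24 with the slide as a block, 0.13 within slide 1 and 0.34 within slide 2. None of the 4 genes was called by limma with the slide or the replicate block. leuS, lysS and tyrZ were also not called without ccpA replicate 2 (0.101, 0.106 and 0.1) or 3 (0.0949, 0.104 and 0.103) or ccpA topA(S478P) replicate 2 (0.081, 0.0984 and 0.128). lysS and tyrZ were not called without ccpA topA(S478P) replicate 1 (0.0918 and 0.0894), and tyrZ not without ccpA replicate 1 (0.0682) or with median centring (0.122). Shifting the authors' values to the median used here ended the call of the list (camera adjusted p = 0.0635) and of lysS (0.0711). Leaving out both arrays numbered 3 ended the call of the list (camera adjusted p = 0.0713) and of the same 3 genes (0.0916, 0.0912 and 0.0619).

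**Figure D4:**
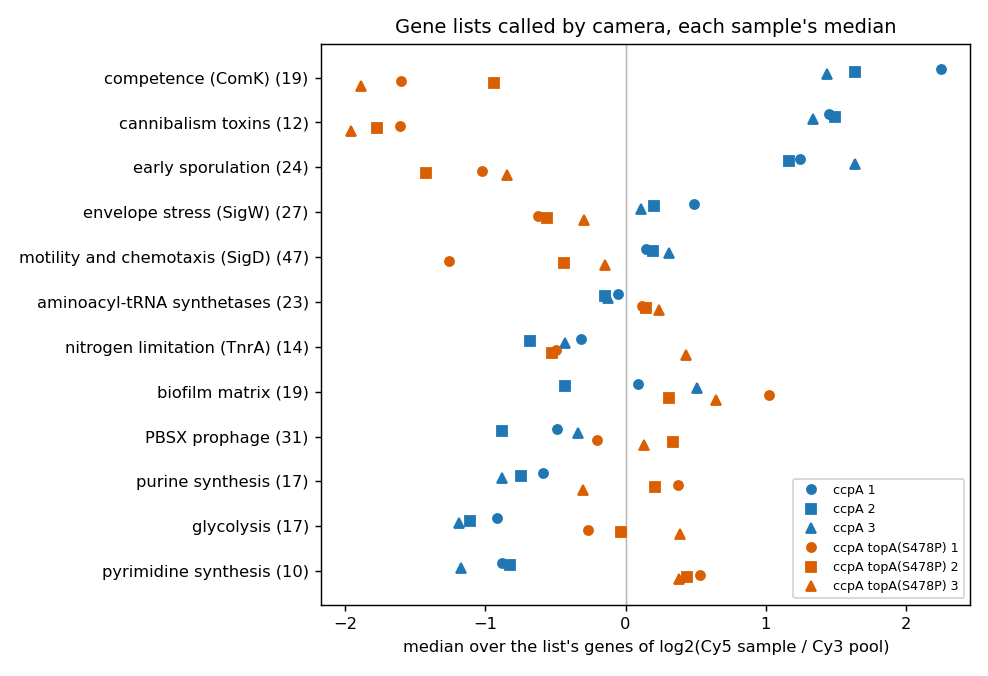
Median over each list's genes of the log2 ratio of Cy5 sample to Cy3 pool (horizontal axis) for the 12 lists called by camera, with 1 point per sample and the number of genes in brackets. The competence list lies between 1.43 and 2.25 in ccpA and between -1.89 and -0.94 in ccpA topA(S478P), and the pyrimidine list between -1.18 and -0.82 and between 0.39 and 0.53.

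The biofilm matrix list was called by camera with 0 of its 19 genes past the test for single genes (0 adjusted over the list alone), a median of 0.66, an adjusted p = 0.0101 and p = 0.822 with an estimated correlation; with the slide as a block camera gave an adjusted p of 0.0609, and the median was 0.45 with that block, 0.92 within slide 1 and 0.09 within slide 2. The call also ended without ccpA replicate 2 and without ccpA topA(S478P) replicate 1 (camera adjusted p = 0.0751 and adjusted p = 0.0624), and fry did not call the list (adjusted p = 0.291). Of the 34 lists 12 were called in all. These calls rest on the preset correlation, and none held with an estimated one. Other divisions of the 6 arrays gave between 11 and 20 called lists. Each of those mixes the strains unevenly and keeps part of their difference, so these counts give no null level for list calls.

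Several lists that were not called over all arrays also held called genes. Of all features kept, 26.8% were called. Of 23 genes for surfactin, bacillaene and bacilysin, srfAA, srfAB, srfAC and srfAD of surfactin synthesis fell, with differences between -0.97 and -0.74, and 3 pks genes rose. The srf falls depended on the scaling: with the Cy5 signal alone srfAB, srfAA and srfAC differed by -0.24, -0.21 and -0.16 (limma adjusted p = 0.281, 0.302 and 0.414), and with median centring by -0.57, -0.45 and -0.48 (0.272, 0.371 and 0.28). Of 14 genes under the DNA damage repressor LexA, 3 fell: recA, the recombinase, which is also induced in competent cells, with -1.34 ± 0.24, tagC with -1.55 ± 0.41 and dinL with -0.90 ± 0.23. In the iron starvation list of 23 genes, 5 rose, with fecD at 1.20 ± 0.20, fecE at 1.03 ± 0.17 and efeB at 0.85 ± 0.17, and 1 fell; 6 rose and 3 fell when adjusted over the list alone. Of 8 histidine synthesis genes, hisA and hisF fell, hisF with -0.97 ± 0.25 (4 fell when adjusted over the list alone). That list, with a median of -0.92 and a camera adjusted p of 0.0676, was called lower with the replicate block (0.0158), the scanner's log ratios (0.042), the authors' values (0.0417), the series matrix (0.042) and the Cy5 signal alone (0.028). It was also called without ccpA replicate 3 (0.0494) or ccpA topA(S478P) replicate 1 (0.0257) or 2 (0.0325). Single genes were called in 5 further lists: ilvC among 9 for branched-chain amino acids (-0.55 ± 0.16), aroE, which the array files call aroD, among 17 for aromatic amino acids (0.83 ± 0.14), fabL among 13 for fatty acid synthesis (0.63 ± 0.15), rsiX among 7 for D-alanylation and sigma factor X (-1.03 ± 0.26), and yfhD among 31 of the general stress list (-3.54 ± 0.54). Adjusted over the list alone, the first and the third of these 5 lists gave 0 calls and the others 1 each. No gene was called among 49 ribosomal proteins, 9 of ATP synthase, 18 of the respiratory chain, 17 heat shock and chaperone genes, 8 of arginine degradation, 9 of arginine synthesis, 13 of methionine and cysteine synthesis or 17 of phosphate starvation, also when adjusted over each list alone. Of the genes named in this paragraph, srfAB alone was also called with the slide as a block. Leaving out 1 sample ended the calls of srfAA, tagC, dinL, efeB, hisA, hisF, ilvC, fabL and rsiX in at least 1 case each (limma adjusted p between 0.0503 and 0.153). ilvC was also not called with the scanner's or the authors' values or with median centring (limma adjusted p = 0.0965, 0.0963 and 0.463), with the mean over probes (0.0558), the Cy5 signal alone (0.0581) or the replicate block (0.0847). dinL was not called with the Cy5 signal alone (0.0816), hisA not with median centring (0.0558) or the Cy5 signal alone (0.056), and fabL, srfAA and srfAD not with the replicate block (0.0612, 0.057 and 0.0558). At an unadjusted p under 0.05, 2239 of all features passed. The ribosomal and ATP synthase lists had medians of 0.15 and 0.28, which became 0.46 and 0.62 and were called by camera when the arrays were centred on the median without loess. The ATP synthase list, with a camera adjusted p of 0.0504, was also called with the replicate block (0.0492), without the filter on dim probes (0.0486), without ccpA replicate 1 (0.046) and by fry (0.00112). Median centring also called as higher the lists of surfactin, bacillaene and bacilysin (camera adjusted p = 0.0232), iron starvation (0.0494), carbon catabolite repression (0.0232) and acetate, acetoin and lactate (0.0295). Leaving out ccpA topA(S478P) replicate 3 called the first 2 of these 4 (0.0427 and 0.022). The carbon catabolite repression list was also called with the replicate block (0.0379) and without ccpA replicate 1 (0.00713) or ccpA topA(S478P) replicate 1 (0.00541) or 2 (0.0377). The acetate list was called without ccpA replicate 1 (0.0408) or ccpA topA(S478P) replicate 2 (0.0477) and by fry (0.004).

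Replicate 3 of ccpA topA(S478P) differed from the others of its strain in several of these lists. Its median was 1.77 for the general stress genes under sigma factor B, against -1.30 and -1.55 in replicates 1 and 2, and 2.39 for the phosphate starvation genes, against -0.68 and -0.65. Over all arrays limma's camera called neither list, with adjusted p = 0.595 and adjusted p = 0.963. Without this replicate limma's camera called both as lower, with medians of -0.64 and -0.74 (adjusted p = 0.0002 and 5.49e-05). The within-slide medians also opposed each other, -1.10 within slide 1 and 1.02 within slide 2 for general stress, and -1.15 and 0.82 for phosphate starvation. In a list of 7 fermentation genes under the redox regulator Rex, written after the data had been seen, none was called; its median was 1.54 in replicate 3 and -3.78 and -3.27 in replicates 1 and 2. The arginine synthesis list lay at -1.58 in replicate 3 and at -0.11 and 0.71 in replicates 1 and 2. Among the ccpA samples, replicate 1 was the highest for the general stress genes, at -0.07 against -1.08 and -0.86 in replicates 2 and 3.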

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

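The alternatives without the arrays numbered 3 and with the authors' values shifted by a constant were chosen after seeing the data; the others were planned. Counts within 1.5 times of those reported are given as ranges. The 548 higher features became 946 with the scanner's log ratios, 945 with the authors' gene-level values, 947 with the series matrix and 1055 with the Cy5 signal alone, all of which leave the median feature about 0.23 higher in ccpA topA(S478P); the authors' values shifted to the median used here gave 630 higher and 1005 lower. They became 149 at an adjusted p under 0.01 and 102 with the slide as a block. Leaving out 1 sample gave 202 (without ccpA topA(S478P) replicate 2) to 818 (without replicate 3 of that strain); without ccpA replicate 1, 2 and 3 the counts were 259, 221 and 223. The cause was not tested beyond the smaller number of samples. The 988 lower features ranged from 660 with the slide as a block to 1160 without ccpA topA(S478P) replicate 3, and the 951 changed at least 2-fold from 739 with the slide as a block to 1287 with the scanner's log ratios. Without both arrays numbered 3, 549 features were higher and 1082 lower. Features called both here and under an alternative had the same direction in each case. Quantile normalization of the average intensities leaves log ratios as they are, so it tests nothing.

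The 12 called lists ranged from 10 to 18 under the other alternatives and became 0 when camera estimated the correlation within each list, at adjusted p from 0.504 to 0.991; camera at the preset correlation treats members of an operon as nearly independent. At an unadjusted p under 0.05 with an estimated correlation, 3 lists passed. By fry, which asks whether a list's genes change and not whether they change more than others, 10 were called. These were early sporulation, competence, cannibalism toxins, glycolysis, purines, pyrimidines, envelope stress, aminoacyl-tRNA synthetases, acetate and ATP synthase. The median of the general stress list, 0.42 and not called, turned to -0.64 and was called lower without ccpA topA(S478P) replicate 3, and to -0.80 without both arrays numbered 3; without replicate 2 it was 1.00 and called higher. This list is set by replicate 3. No other list and none of the 86 named genes changed direction with a call on either side. Of the named genes, 41 lost their call with the slide as a block and 11 with the replicate block. The slide block takes ccpA replicate 2, alone on its slide, out of the difference, and both blocks leave less information for the error. Calls can thus be lost without a change in the difference.

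Both strains carry replicate numbers 1 to 3. Across features, deviations from the group means correlated at r = -0.36, 0.31 and -0.05 for samples numbered 1, 2 and 3, so only those numbered 2 deviated together. Deviations from a mean of 3 samples sum to 0, so these values are tied to one another and are no independent test of pairing. Of the 6 samples only ccpA topA(S478P) replicate 2 correlated best with its own number, and the numbers were not taken as pairs. With the replicate block, 276 features were higher and 856 lower. Signal over background was 15.7 in Cy5 for ccpA topA(S478P) replicate 3 and 21.4 to 34.1 for the others. Of the lower features, 30, of which 6 were annotated genes, were not well above background on any array of ccpA topA(S478P). The stricter filter on dim probes, which kept 5436 features, gave 804 lower against 988 and 500 higher against 548. The 30 thus need not include all falls that dimness limits.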

Other observations

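The genes described first were chosen after their values were seen, and the tests below were chosen after the patterns were seen, except those on other divisions of the arrays and on the order of genes along the chromosome. Single genes outside the lists that rose are given here without a test of any theme. lysP, a lysine permease, rose by 2.08 ± 0.18 (SE) and lysCA, an aspartokinase of lysine synthesis, by 1.92 ± 0.17 (limma adjusted p = 0.000296 and 0.000365), and both were higher in 3 of 3 samples. The neighbouring genes thiU, thiV, thiW and thiX, for the uptake of a thiamine precursor, rose by 1.92 ± 0.19, 1.69 ± 0.18, 1.77 ± 0.18 and 1.63 ± 0.19. pbuO, a purine transporter, rose by 1.82 ± 0.22, tcyP, a cystine transporter, by 1.67 ± 0.19 and braB, a transporter of branched-chain amino acids, by 1.95 ± 0.19. These 9 genes were also called with the slide as a block.

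In ccpA replicate 1 the neighbouring genes ndhF, ybcC, ybcF, ybcH and ybcI had log2 ratios of -4.36, -4.36, -4.15, -3.84 and -3.63, and those of the other 2 ccpA samples lay between -1.11 and -0.65. None was called between the strains.

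With 6 arrays in 2 groups of 3 there are 10 divisions, too few for a share under 0.05. The real division gave 548 higher, 988 lower and 951 features changed at least 2-fold, and the highest of the other 9 gave 0 for each, so it was the only 1 of the 10 with as many. For lists, 9 of the 10 divisions gave at least the 12 of the real one, up to 20, among them the division that sets slide 2 against slides 1 and 3, which gave 12. Each of the other 9 divisions sets 2 arrays of 1 strain with 1 of the other, so part of the strain difference stays in it. List calls there can reflect the strains, and mixing them widens the spread within groups, which lowers gene calls. The divisions thus do not show whether list calls follow other structure among the samples. The list medians with the slide as a block and within slides stand beside each list in the results.

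Replicate 3 of ccpA topA(S478P) stood apart from replicates 1 and 2. Of the 100 genes that differed most, 98 were higher in replicate 3, and 52 of the 100 had a chromosomal neighbour among them that moved the same way, against at most 21 in 10000 random sets, which argues against a fault of the array. Replicate 2, on the same slide, correlated with replicate 1 on another slide at r = 0.8925 and with replicate 3 at r = 0.50, which argues against the slide. The early sporulation list lay at -0.85 in replicate 3, far below the 1.35 ± 0.25 (SD, n = 3) of the ccpA samples. That argues against a swap with RNA of the other strain. It cannot exclude a small admixture, since replicates 1 and 2 were lower, at -1.03 and -1.42. The general stress and phosphate starvation medians of replicate 3, 1.77 and 2.39, lay above those of all ccpA samples (highest -0.07 and 0.68). A mixture of the strains alone would not give that. The pattern may be a difference in the state of that culture. lctE, lctP, cydA and cydB, which respond to the redox state, were at 0.84, 0.85, 1.59 and 1.97 there and at -3.27 or below in replicates 1 and 2. These genes were not shifted in that culture alone. In ccpA replicate 1 lctE was at -1.63, against -7.315 and -7.02 in the other ccpA samples, and lctP at -2.95 against -7.25 and -6.82. There cydA was at -2.74 against -5.72 and -5.38, and cydB at -2.47 against -3.75 and -3.18. The labels name no such difference and no biological explanation was tested.

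A set of 11 genes lay below the pool on all 6 arrays, with a mean linear ratio over the arrays under 0.25: pftA and pftB, alsS and alsD, gltA and gltB, cidA and cidB, cesA, yrhP and yuiA. The ratio was not that low on each array: in ccpA topA(S478P) replicate 3 gltA, cidB, cidA and gltB had log2 ratios of -0.97, -1.05, -1.14 and -1.29. A dye bias of their probes is argued against, since 8 of the 11 lie beside another of the set, against at most 4 in 10000 random sets, and so is a dim pool signal, since their median pool signal lay at the 78.9th percentile of all genes. The pool may hold RNA from beyond these 6 samples: a pool of equal parts of them would give mean ratios near 1, but the median over these genes stayed at or below 0.155 under 4 scalings, while the late sporulation list had a median mean ratio of 1.73. What else the pool held is not given in the labels. Both strains are set against the same pool, so it cancels in the differences between them.

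In ccpA replicate 3 the median log2 ratio of the sigma factor K list was 0.46, against 2.33 and 1.70 in the other ccpA samples, a difference of -1.55 from their mean, with 29 of its 30 genes below both. Fewer sporulating cells would lower the earlier stages as well, but the sigma factor E list lay at 1.77, above the other 2 samples. Compression on that array would multiply log ratios by a factor below 1, but the SD over the genes outside the list was 0.72, which is 100.1% of the lower SD of the other ccpA samples, and the median log2 ratio of the sigma factor G list was 1.17, which is 96.2% of its mean there; the latter is a quotient of log ratios and no share of RNA. A culture taken at an earlier point of the last stage remains a possible explanation; no biological explanation was tested, since the labels give all samples the same OD600.

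A last hypothesis was that the strains differ in gene dosage from replication, which would order the differences by distance from the replication origin. Over 4175 genes, Spearman's rho of the difference with the distance was -0.0799, inside the middle 95% of 4174 rotations of the gene order (-0.0907 to 0.0907), and 31.6% of rotations were as strong. The median difference was 0.13 nearest the origin, 0.04 in the middle and -0.01 nearest the terminus. Rotation keeps any broad gradient and moves its position, so it tests where a gradient lies and not whether there is one. The test thus gives no support for a dosage gradient between the strains and cannot exclude one.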
